A study of Mus musculus with 2 samples.

How the data were processed

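The data are a table of counts per gene symbol for 2 mouse ovary libraries, 1 wild type and 1 H19 knockout, each labelled C57BL/6J and 8 weeks old. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced with paired ends on a NextSeq 500. The deposited values are whole-number counts made by the authors. Per the submitters' processing notes the tools were STAR 2.5.0a, Cufflinks 2.2.1 and DESeq2 1.0.0 with the mm10 build, without their roles or order. The counting tool, annotation and strand setting are not given in the sources used here, so genes that overlap on either strand cannot be separated.

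The values were checked for signs of rescaling, because DESeq2 is among the tools. The median knockout to wild-type ratio of counts was exactly 1 over the 17904 genes with counts in both libraries, of which 727 had equal counts, but 0.985 for genes with more than 200 counts. Rescaling whole reads upwards and rounding leaves gaps: a factor of 1.05 would leave no gene with 11 counts, whereas the lowest absent whole number was 527 in the wild type and 937 in the knockout. Normalisation of values that were not whole, followed by rounding, cannot be excluded. In that case the counting intervals would be slightly off and the ratios would carry the authors' scaling.

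The table held 24421 rows, of which 23309 matched a symbol of the GENCODE M21 annotation, which is on the same build and gave coordinates and gene types. A further 27 rows carried dates in place of gene symbols. They held 0.229% of wild-type and 0.231% of knockout counts, were kept in the totals and were not named. The mitochondrially encoded list had 0 rows in the table and the red blood cell list 1 measured gene, so neither has a percentile.

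Libraries were scaled by TMM (edgeR 4.0.16). Log2 ratios are of scaled counts with 0.5 added. For each gene the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio was computed. It covers counting error only, not differences between animals or preparations. At a mean of 1 to 2 CPM the median interval was 1.53 log2 units wide, and above 100 CPM 0.130. A count of 0 was taken to allow 3 counts, which is 0.129 CPM in the wild type and 0.130 in the knockout. A gene was counted as higher or lower when its mean was at least 1 CPM and its whole interval lay beyond 2-fold. This is a fixed rule of size, not a significance test, since 1 library per genotype allows none.

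The 26 gene lists, the size rule, the rule for named genes and the alternatives were chosen before the data were examined. Named genes were H19 and Igf2, the 15 genes farthest beyond 2-fold in each direction by the nearer interval bound among genes of at least 1 CPM, and from each list up to 4 of the most abundant measured members and up to 4 beyond 2-fold. Members below that minimum were to be named only with their counts. A gene that this rule selects is not reported here. Each list's median was placed among 10000 random lists of equal size drawn from 20 bins of mean expression, and stood apart at or below percentile 2.5 or at or above 97.5, given at least 3 measured members. The percentile describes these 2 libraries. Lists share some genes, for example Hsd17b7 and Lhcgr.

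The scripts were tested on simulated data drawn from the real means and library sizes, with 13935 genes run. Of 50 genes each, 98.0% raised 3-fold and 92.0% lowered 3-fold were recovered, and all of those altered 6-fold. None of 13735 unaltered genes was called, and 95.3% of their intervals held the true ratio. Draws from means and library sizes hold no measured difference between animals or preparations, so these values are no error rate for the real libraries. A list raised by 0.5 log2 units reached the 100th percentile. Of 200 random lists 9% stood apart, where 5% would by chance. After that share was seen, 1000 further lists with 400 random lists each were run, of which 5.20% stood apart.

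Alternatives were total count scaling, median-of-ratios scaling (DESeq2 1.42.0), library sizes without the 10 most abundant genes, 5 added to each count, no low count filter, a minimum of 5 CPM, the point ratio in place of the interval, limits of 1.5-fold and 4-fold, unmatched random lists, and the mean of list members. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.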

Results

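H19 is an imprinted long noncoding RNA that neighbours the growth factor gene Igf2 and carries the microRNA Mir675 in its transcript. The study sequenced total RNA, depleted of ribosomal RNA, from whole ovaries of 8-week-old C57BL/6J mice, and asked which ovarian genes depend on H19. There were 2 libraries, 1 from a wild-type ovary sample and 1 from an H19 knockout. The wild-type library held 23335131 counts over 18730 genes and the knockout library 23041225 counts over 19556 genes. With 1 library per genotype, no difference below has a replicate check and no p-value is given. All intervals, except those marked as a bootstrap over members, are 95% exact binomial intervals of the knockout to wild-type ratio. The binomial intervals cover counting error only. Each comparison describes these 2 libraries, not the genotypes.

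H19 was present in the wild-type library and had no count in the knockout library. The gene (mm10 chromosome 7, 142575529 to 142578143, minus strand) had 672 counts in the wild type, or 28.9 CPM, and 0 in the knockout. A count of 0 allows up to 3 counts, or 0.130 CPM, so H19 was at least 223-fold lower in the knockout library, as the genotype label states. That bound takes the wild-type count as measured, without its counting error. Igf2, which encodes the growth factor IGF2 and lies on the same strand at 142650766 to 142666816, was higher in the knockout library. It had 632 counts there against 275 in the wild type, a log2 ratio of 1.21 (1.00 to 1.42). The lower bound only just exceeded 2-fold, and under median-of-ratios scaling, with a log2 ratio of 1.20, the interval no longer lay wholly beyond it. The Igf2 row overlaps Mir483 and, on the opposite strand, Igf2os.

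Most of the ovarian transcriptome was close to equal in the 2 libraries, and a small set of genes differed severalfold. Interferon-inducible GTPases and the glucocorticoid-synthesising enzyme Cyp11b1 led the genes higher in the knockout library. Rpl29, Ces2a, Sstr1 and the androgen-synthesising enzyme Cyp17a1 were among the genes farthest lower. Of 13928 genes with a mean of at least 1 CPM, 85 had an interval wholly above 2-fold and 54 an interval wholly below it. The central 95% of genes spanned log2 ratios of -0.67 to 0.79. The median of all measured genes was -0.01, but TMM scaling centres the ratios near 0, so the median is no evidence of similarity. Across genes, which are not independent replicates, log2(CPM + 1) of the 2 libraries had a Pearson correlation of 0.988.

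Of the 15 genes farthest above 2-fold, the largest ratio was that of Cyp11b1, the enzyme that makes corticosterone from deoxycorticosterone. It had 13 counts in the wild type and 945 in the knockout, a log2 ratio of 6.14 (5.41 to 7.11). The immunity-related GTPase Iigp1 had 872 and 7179 counts, a log2 ratio of 3.05 (2.95 to 3.15). Its relatives Tgtp2, Igtp and Tgtp1 had log2 ratios of 2.68, 2.53 (2.36 to 2.72) and 2.42 (2.12 to 2.74). The guanylate-binding proteins Gbp10, Gbp4 and Gbp6 had log2 ratios of 4.70 (3.79 to 6.02), 2.47 and 2.34. Gbp10 had only 8 counts in the wild type and 220 in the knockout. Zbp1, an interferon-inducible sensor of Z-form nucleic acid, had 33 and 287 counts and a log2 ratio of 3.11 (2.61 to 3.69). Gm12250, Gm12185 and Gm6093 had log2 ratios of 3.09, 2.73 and 3.36. The others were Pappa2, a protease that cleaves IGF-binding proteins (20 and 319 counts, 3.97), Adh7, an alcohol and retinol dehydrogenase (66 and 573 counts, 3.12), and the serpin Serpina3f (12 and 147 counts, 3.57). Tgtp1 and Tgtp2 are near-identical copies, Igtp overlaps Irgm2, Gbp4 overlaps Gbp8 and Gbp9, and Gm12185 overlaps Tgtp1, so the split of reads among these rows is uncertain. On the opposite strand, Cyp11b1 overlaps Gml2, Adh7 overlaps 0610031O16Rik, and Tgtp1, Tgtp2 and Gm12185 overlap Olfr56. The strand setting is not given, so these cannot be separated either.

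After H19, the gene farthest below 2-fold was Trim12a, a TRIM-family gene with 77 counts in the wild type and 0 in the knockout. Trim12a was at least 25.5-fold lower by the same allowance of 3 counts, again without the counting error of the wild-type count. Rpl29, which encodes a protein of the large ribosomal subunit, had 7435 and 328 counts, a log2 ratio of -4.49 (-4.66 to -4.33). The carboxylesterase Ces2a had 674 and 60 counts (-3.47), and the somatostatin receptor Sstr1 had 1151 and 168 (-2.76). Cyp17a1, the theca cell enzyme that makes androgens, had 11243 and 2834 counts, a log2 ratio of -1.98 (-2.04 to -1.92). Grem1, a secreted BMP antagonist, had 355 and 81 counts (-2.12), and Tdgf1, a Nodal co-receptor, 99 and 14 (-2.77). The remaining 7 genes had log2 ratios between -3.20 and -2.35. They were Cdsn, Podnl1, the calcium-binding protein gene S100g, Trim30d, Dab1, the glycine decarboxylase Gldc and the lincRNA 2610035D17Rik, with Podnl1 at 307 and 57 counts (-2.41). On the opposite strand, Trim12a overlaps Gm15133 and S100g overlaps Ctps2.

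**Figure D1:**
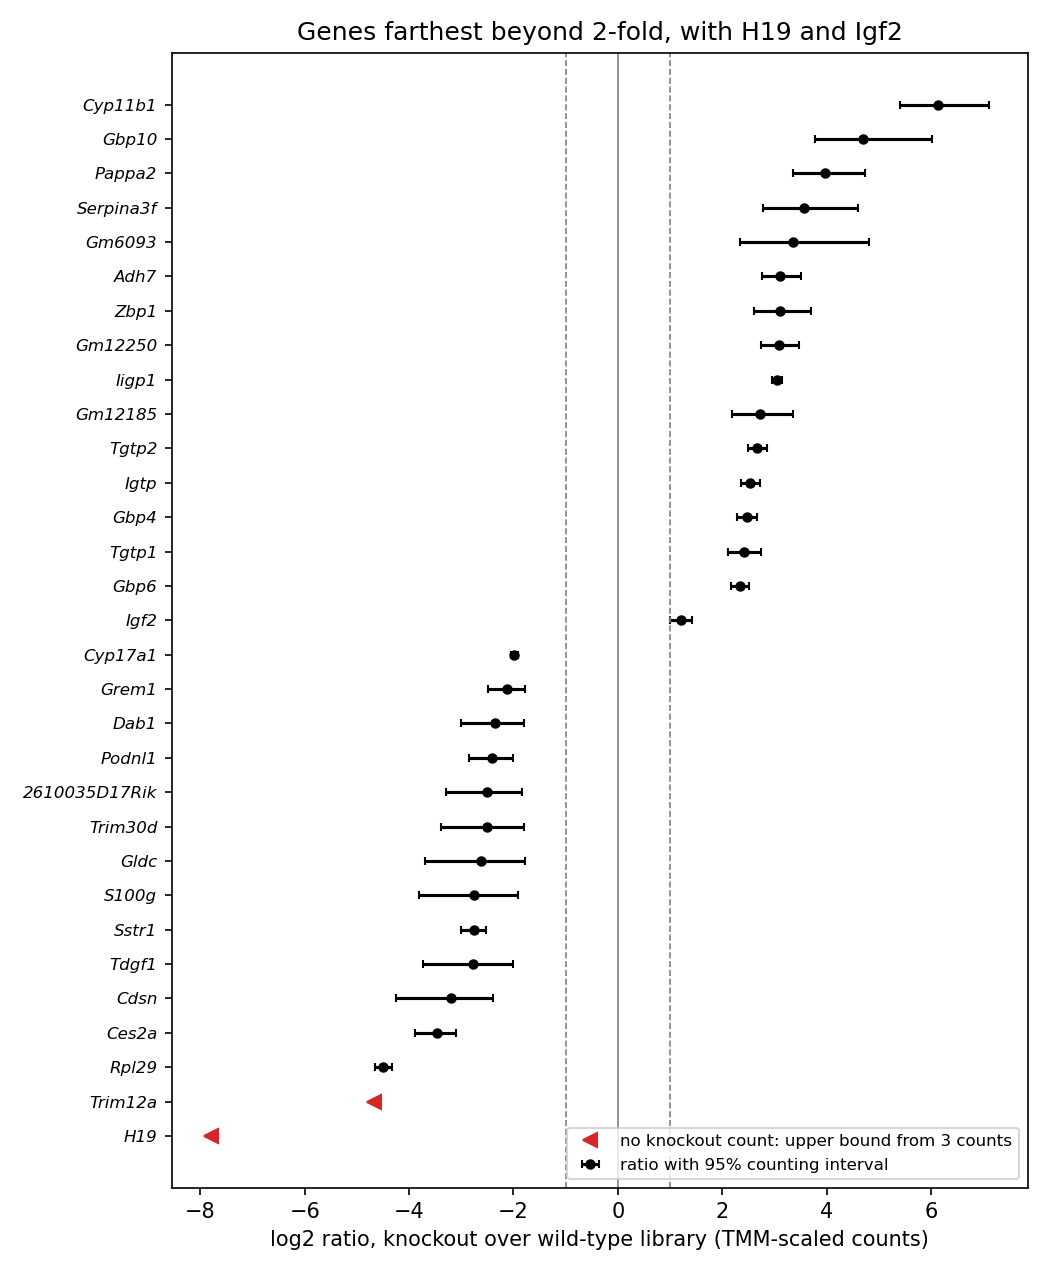
Log2 ratio of the knockout over the wild-type library (x axis) for Igf2 and for the 15 genes farthest above and the 15 farthest below 2-fold (y axis). Points are ratios of TMM-scaled counts with 95% counting intervals from 1 library per genotype, dashed lines mark 2-fold, and red triangles mark H19 and Trim12a, with 0 knockout counts, at the bound that 3 counts give. Cyp11b1 lies at 6.14 and Rpl29 at -4.49.

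Gene lists fixed before the data were examined were compared by the percentile of their median log2 ratio among 10000 random lists of the same size and expression. Of 24 lists with enough measured members, 6 stood above the central 95% of random lists and 7 below it. For lists of randomly drawn genes 1.20 would lie outside. Genes of a fixed list can vary together and some lists share genes, so that number is no yardstick for these lists. Interferon and antigen presentation genes stood higher in the knockout library. Cholesterol synthesis genes and markers of granulosa, theca, luteal and germ cells stood lower.

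The interferon response list had a median log2 ratio of 0.73 over 21 measured genes, at the 100th percentile. Of its members, 18 had an interval above 0 and none below, and 5 lay beyond 2-fold. Gbp2 had a log2 ratio of 1.73 (1.65 to 1.81), Gbp3 1.47 (1.37 to 1.58) and Irgm1 1.33 (1.23 to 1.44). The list of macrophage and antigen presentation markers had a median of 0.34 over 17 genes, at the 100th percentile. Of these, 14 had an interval above 0 and 1 below, Csf1r at -0.24 (-0.35 to -0.13). The class II gene H2-Ab1 had a log2 ratio of 0.74 (0.68 to 0.80), its chaperone Cd74 0.38 (0.33 to 0.43) and the lysozyme gene Lyz2 0.54 (0.48 to 0.61). Lymphocyte markers had a median of 0.07 over 6 genes of low count, at percentile 54.3; Cd4 had 127 and 93 counts.

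Cholesterol synthesis and uptake genes had a median log2 ratio of -0.41 over 21 genes, at percentile 0, and 20 of the 21 had an interval below 0. Hsd17b7, which acts in both cholesterol and oestradiol synthesis, had 15971 and 8094 counts, a log2 ratio of -0.97 (-1.01 to -0.93). Cyp51, which demethylates lanosterol, had one of -0.53 (-0.59 to -0.48), and Hmgcs1, an early enzyme of the mevalonate pathway, -0.37 (-0.40 to -0.34). None of these members lay beyond 2-fold.

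The steroid hormone synthesis list had a median of -0.09 over 18 genes, at percentile 3.53, inside the random range, and its members went in both directions. Star and Cyp11a1, which deliver cholesterol to and start steroid synthesis, had log2 ratios of 0.11 (0.09 to 0.13) and -0.02 (-0.03 to -0.01). Hsd3b1, the most abundant member at 195244 and 186482 counts, had one of -0.06. Aromatase, Cyp19a1, had 1052 and 345 counts, a log2 ratio of -1.60 (-1.78 to -1.42). The HDL receptor Scarb1 had one of -0.47 (-0.49 to -0.44). Beyond 2-fold were Cyp11b1 on the higher side and Cyp17a1 and Cyp19a1 on the lower.

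Granulosa cell markers had a median of -0.31 over 20 genes, at percentile 0, with 16 intervals below 0 and 2 above. Cyp19a1 and the hedgehog ligand Ihh lay beyond 2-fold, Ihh with 1070 and 454 counts and a log2 ratio of -1.23 (-1.39 to -1.07). The inhibin subunit Inha had a log2 ratio of -0.50 and the gap junction gene Gja1 -0.35, whereas Nr5a2 had 0.04 (0.01 to 0.07). Theca and interstitial markers had a median of -0.32 over 11 genes, at percentile 0.0100, but were mixed. Cyp17a1 was far lower and the luteinising hormone receptor Lhcgr had a log2 ratio of -0.51, while Mgarp had 0.68 (0.64 to 0.71) and Aldh1a1 0.27 (0.26 to 0.29). Corpus luteum markers had a median of -0.32 over 12 genes, at percentile 0, and the prolactin receptor Prlr had -0.18 (-0.20 to -0.16). Oocyte markers had a median of -0.28 over 30 genes, at percentile 0, with 17 intervals below 0, none above and none beyond 2-fold. Among them the zona pellucida gene Zp2 had a log2 ratio of -0.36 (-0.47 to -0.26) and Padi6 -0.40 (-0.50 to -0.31).

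Ovulation response genes had a median of 0.40 over the 12 measured genes of 19, at percentile 99.98. Of the 12, 6 had an interval above 0, 2 below it and 4 spanning it. The 4 spanning 0 were Pgr, Has2, Ptx3 and Cd44, and the 6 above included Ptgs2, with only 18 and 46 counts. The protease Adamts1 had 2069 and 4500 counts, a log2 ratio of 1.13 with its interval beyond 2-fold, and the transcription factor Runx1 2178 and 4519, 1.06 (0.99 to 1.14). Vcan, a matrix proteoglycan, and Runx2 were lower, at -0.45 and -0.38.

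Stromal and surface lists stood higher by smaller amounts. Extracellular matrix genes had a median of 0.13 over 28 genes, at percentile 99.99, with 19 intervals above 0 and 7 below. The collagen Col3a1 had a log2 ratio of 0.56 (0.54 to 0.59) and the proteoglycan Dcn 0.63 (0.59 to 0.66), but the basement membrane collagen Col4a1 had -0.16 (-0.19 to -0.14). Smooth muscle and pericyte markers had a median of 0.19 over 12 genes, at percentile 99.9, with 8 intervals above 0 and 3 below. The smooth muscle myosin Myh11 was highest at 0.60 (0.56 to 0.64). The 3 below were the pericyte markers Pdgfrb at -0.35 (-0.42 to -0.28), Cspg4 at -0.41 (-0.58 to -0.25) and Rgs5 at -0.17 (-0.29 to -0.06). The higher median did not extend to these 3. The mean of the list, 0.12, lay inside the random range. Ovarian surface epithelium markers had a median of 0.25 over 11 genes, at percentile 99.8, with Upk3b at 0.62 (0.47 to 0.78) and Lgr5 at -0.33 (-0.46 to -0.20). Endothelial markers stood lower, with a median of -0.18 over 14 genes at percentile 0.230. Of the 14, 8 had an interval below 0, 5 spanned it and 1 lay above, Cldn5 at 0.23 (0.09 to 0.37). Pecam1 had a log2 ratio of -0.36 (-0.44 to -0.28) and Cdh5 -0.27 (-0.33 to -0.21).

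**Figure D2:**
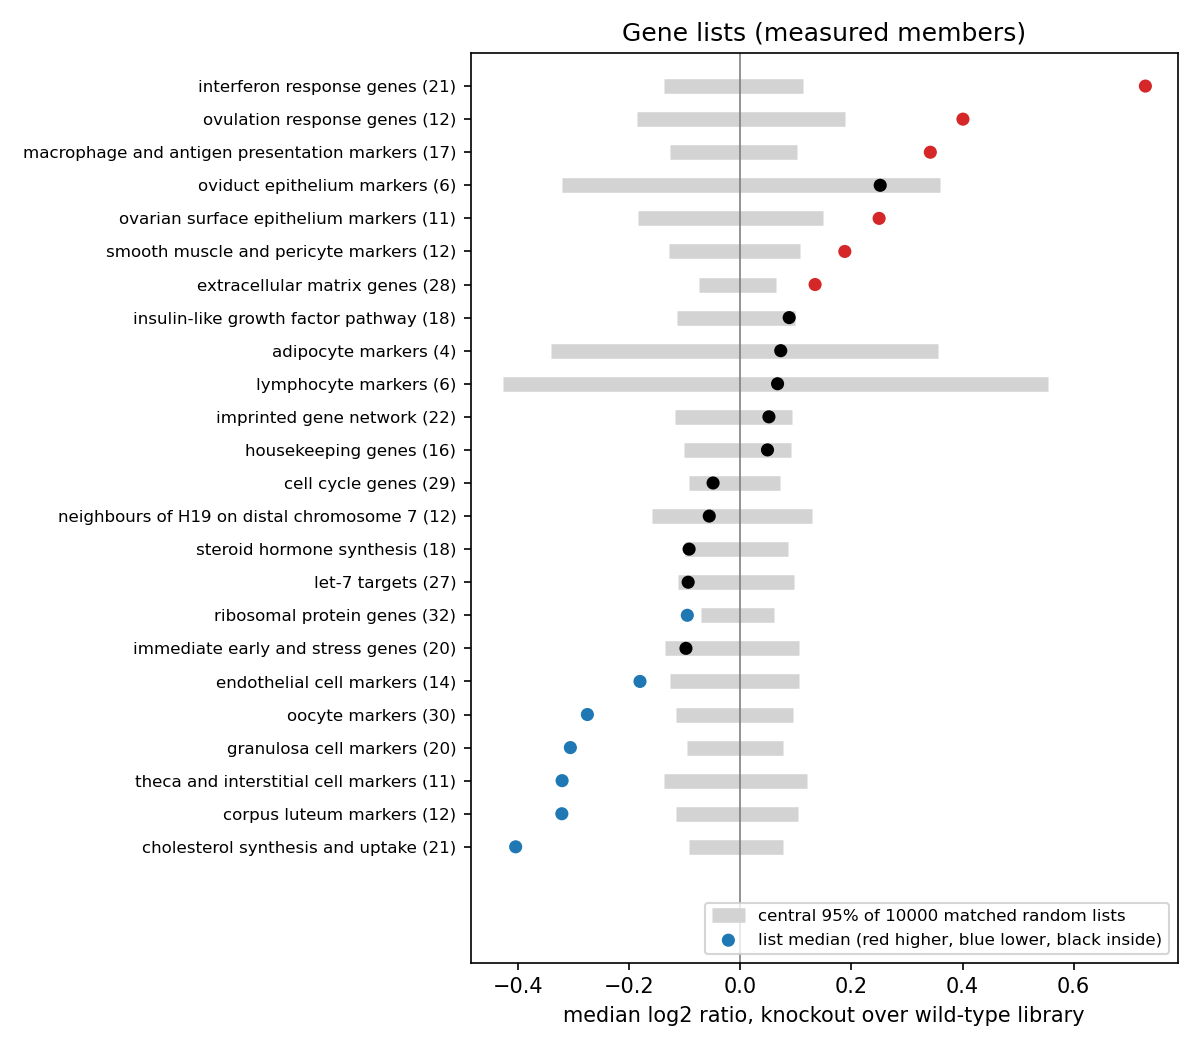
Median log2 ratio of the knockout over the wild-type library (x axis) for each gene list (y axis, with the number of measured members). Points are list medians and grey bars the central 95% of 10000 random lists of equal size and expression, from 1 library per genotype. The interferon response list lies highest at 0.73 and the cholesterol list lowest at -0.41.

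The lists closest to the known partners of H19 lay inside the random range. The imprinted gene network had a median of 0.05 over 22 genes, at percentile 88.3. Of the 22, 8 had an interval above 0, 4 below it and 10 spanning it. Apart from Igf2 none of the members lay beyond 2-fold. Peg10 had a log2 ratio of 0.57 (0.52 to 0.62), Gnas 0.13 and Igf2r 0.05 (-0.00 to 0.11). On the lower side, Mest had -0.88 (-1.03 to -0.73) and Nnat -0.74 (-0.84 to -0.64). The neighbours of H19 on distal chromosome 7 had a median of -0.06 over 12 genes, at percentile 28.6, with Ctsd at 0.22 (0.18 to 0.25), Cd81 at 0.08 and Nap1l4 at -0.07 (-0.15 to 0.01). Targets of let-7, a microRNA that H19 can bind, had a median of -0.09 over 27 genes, at percentile 4.76. Of these, 11 had an interval below 0, 1 above it and 15 spanning it. In the insulin-like growth factor pathway the median was 0.09 over 18 genes, at percentile 96.1, with Igf2 and Pappa2 beyond 2-fold, Igfbp5 at 0.15 and Igf1r at -0.17 (-0.22 to -0.13). The mean of that list, 0.28, lay above the random range.

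Ribosomal protein genes had a median of -0.10 over 32 genes, at percentile 0.310, but their mean of -0.06 lay inside the random range, as did the median against unmatched lists. Rpl4 had a log2 ratio of -0.12 and Rps4x 0.09. Cell cycle genes had a median of -0.05 over 29 genes, at percentile 17.1, with Mki67 at -0.15 and Top2a at 0.02 (-0.04 to 0.07). Immediate early and stress genes had a median of -0.10 over 20 genes, at percentile 8.84, and went both ways, with Jun at 0.65 (0.58 to 0.73) and Nr4a1 at -0.82 (-0.91 to -0.73). Housekeeping genes had a median of 0.05 over 16 genes, at percentile 86.2, with Actb at 0.06 and Eef1a1 at 0.04; the class I light chain B2m, which is also interferon-inducible, had 24612 and 49236 counts and a log2 ratio of 1.01 (0.99 to 1.03). Markers of tissue that can adhere to a dissected ovary gave few measured genes. Oviduct markers had a median of 0.25 over 6 genes, at percentile 92.3, and the oviduct secretory gene Ovgp1 had 33 and 134 counts. Adipocyte markers had a median of 0.07 over 4 genes, at percentile 68.5, and the lipid droplet gene Plin4 had 12643 and 5650 counts, a log2 ratio of -1.15 (-1.20 to -1.11). Of the red blood cell markers 1 was measured, Alas2, with 89 and 44 counts.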

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

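The alternatives were chosen before the data were examined, and none was added. H19 was at least 221-fold lower under total count scaling and at least 224-fold lower under median-of-ratios scaling. Under the 3 other scalings, 82 to 86 genes were higher and 54 to 55 lower. With a minimum of 5 CPM, 34 genes were lower, because fewer genes were counted. The point ratio gave 206 higher and 123 lower genes, the 1.5-fold limit 251 and 168, and the 4-fold limit 16 and 7, as a looser or stricter rule must. Of 189 list values under alternatives, 178 kept their direction and their side of the random range. The sign turned, inside the random range, for the neighbours of H19 with no low count filter (0.0415) and by the mean (0.0479), and by the mean for steroid hormone synthesis (0.00829) and adipocyte markers (-0.11). By the mean of members, the insulin-like growth factor pathway moved above the random range (0.28), smooth muscle markers (0.12) and ribosomal protein genes (-0.0581) moved inside it, and ribosomal protein genes also did so against unmatched lists (-0.10). Oviduct markers (0.25) stood apart against unmatched lists. Adipocyte markers, with 4 measured genes, stood apart at 0.57 without the most abundant genes in the library size and, with the sign turned, at -0.53 with no low count filter, since their measured members differ between these settings; otherwise the cause was not tested. Named-gene values were compared by direction and, under the 3 other scalings, by side of 2-fold. With 5 added to each count, the value had to stay inside the gene's interval instead. Of 500 values, 498 held. The exceptions were Igf2 (1.20) and Lck, with equal counts and a log2 ratio of 0, both under median-of-ratios scaling. Adding 5 to each count does not enter the intervals, so it gave no value for the counts of genes or for the H19 bound. No paired analysis was possible because each genotype had 1 library, which also rules out leaving out replicates or splitting samples. Depth limits genes near 1 CPM, where the median interval spanned 1.53 log2 units.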

Other observations

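The gene groups and tests here were chosen after the results were seen, except the test of individual animals and that of pseudogene rows, and all describe 1 library per genotype. A group picked from genes already seen to differ will tend to stand apart from random lists. The percentiles of the class I, chaperone, fatty acid and short RNA groups are therefore descriptions and no evidence. Class I antigen processing genes were higher in the knockout library. All 11 had an interval above 0, 4 lay beyond 2-fold, and their median log2 ratio was 0.89, at the 100th percentile of random lists. The immunoproteasome subunit Psmb9 had 94 and 380 counts (2.02, 1.69 to 2.36), Psmb8 310 and 849 (1.46), the class I transactivator Nlrc5 304 and 848 (1.49) and the peptide transporter Tap1 595 and 1445 (1.29). Endoplasmic reticulum chaperones were lower: 13 of 14 had an interval below 0, with a median of -0.32 at percentile 0. Hspa5 had 29586 and 19640 counts (-0.58, -0.61 to -0.56), Hsp90b1 44909 and 31845 (-0.49) and Calr 53354 and 38200 (-0.47). Fatty acid synthesis and desaturation genes had a median of -0.28 over 10 genes, 8 of them with an interval below 0, at percentile 0.0200. The desaturases Scd2 and Fads2 had log2 ratios of -0.62 and -0.59, while Acly had 0.02 (-0.01 to 0.05).

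Short structured RNAs were lower in the knockout library: 24 of 25 had a lower ratio and 14 an interval below 0, with a median of -0.61 at percentile 0. The RNase P RNA Rpph1 took 0.866% of wild-type and 0.573% of knockout counts, and Rmrp had a log2 ratio of -0.64 (-0.65 to -0.62). Xist, the RNA that silences an X chromosome, had 16436 and 8181 counts, a log2 ratio of -0.998 (-1.04 to -0.96). The 469 measured X-linked genes had a median of -0.01, at percentile 61.3.

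Interferon-inducible genes were higher in the knockout library. Leukocyte markers other than Cd74, H2-Aa, H2-Ab1 and H2-Eb1, 19 genes, had a median log2 ratio of 0.28. Whether interferon induces any of the 19 was not tested. The leukocyte minus interferon difference was -0.45 (bootstrap over members, -0.85 to -0.28), against more leukocytes as the whole cause. Misassigned reads among near-identical copies would spare members outside the multigene families, yet the 9 such members had a median of 0.73, at the 100th percentile. A difference between individual animals, such as an infection, may also account for the pattern and cannot be told apart from genotype with 1 library per genotype.

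Rpl29, Trim12a, Trim30d and Ces2a were far lower in the knockout library. A chromosome segment around H19 carried along with the knockout allele cannot hold Rpl29 and Ces2a, since 0 of them lie on chromosome 7. Segments on other chromosomes were not tested. Trim12a and Trim30d lie 38.3 and 38.1 Mb from H19, and the share of genes beyond 2-fold within 45 Mb was at percentile 78.9 of other windows. That window was set after the data were seen, wide enough to include both genes, which count in its share, so the value decides nothing and a segment cannot be told apart from genotype for them. A bound of percentile 90 first written for this test would have counted against a segment and was withdrawn after the value was seen. Rpl29 had 7107 fewer counts in the knockout, and the 347 pseudogene rows together gained 1829, too few for reads moved to these rows; other rows were not examined.

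Cyp11b1 was far higher and Cyp17a1 and Cyp19a1 lower in the knockout library. Adrenal tissue would bring other adrenal transcripts, but Cyp21a1, Cyp11b2, Akr1b7 and Mc2r together had 44 counts in the knockout against 945 for Cyp11b1. Their sum was higher than the 14 counts of the wild type, mainly through Akr1b7 (9 and 36), while Mc2r had 3 and 1, so the counts speak against adrenal tissue as the whole cause only. An even loss of granulosa and theca cells would lower all their markers alike. The other 29 markers had a median of -0.27 (bootstrap over members, -0.46 to -0.12), far above the ratios of Cyp17a1 and Cyp19a1. These values speak against an even loss as the whole cause only. A loss of only part of these cells was not tested. Different stages of the oestrous cycle may account for the pattern. The ovulation response list stood higher at 0.40 but was mixed, with 6 intervals above 0, 2 below it and 4 spanning it. With 1 ovary sample per genotype, stage and genotype cannot be told apart.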
